A study of Mus musculus with 9 samples.

How the data were processed

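RNA from the right ventricle of male mice was measured on Affymetrix GeneChip WT arrays, with 1 array for each of 9 samples. The labels give 3 groups of 3 arrays: wild-type mice on a vitamin A sufficient diet, Lrat-/- mice on the sufficient diet and Lrat-/- mice on a vitamin A deficient diet. The design text does not say that the samples are separate animals, so the p-values measure only the spread between these samples, which may be partly technical. The number of arrays limits the precision.

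The deposited series table holds log2 signals made by the authors with RMA, that is, background correction, quantile normalization and summary by probe set. The submitters' processing notes name RMA, R 3.1.2 and the mm8 build. A second deposited table pairs the probe sets with text annotation and holds 9 columns of RMA values whose names match no sample label. Those values were not used. Its column names carry 2 different dates, 6 columns with one and 3 with the other, and these are not tied to samples. The third deposited table holds the authors' ratio of group means, p-value and false discovery rate for each of 35556 probe sets. Per the file headers it came from an analysis of variance with scan date as a factor. Its highest scan date sum of squares was 1.82e-12, so scan date had been removed before that analysis. Its residual degrees of freedom were 5. The authors' ratios and p-values are given only where they are named as theirs.

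Of the 35556 probe sets, 6546 were array controls and 25464 carried 1 gene symbol. Symbols were updated through a RefSeq gene table of the GRCm38.p6 assembly: 22115 probe sets matched by accession, 1815 by symbol and 625 by synonym, and 909 kept the name in the file. No gene was named for 3543 probe sets without a symbol and 2 with several. The 2 annotated tables named 2450 of 24795 shared probe sets differently. Builds differ between the files and the gene table, which was used only for names and for the order of neighbouring genes. For each of 22060 symbols the probe set with the highest mean over the 9 arrays was kept. The fixed lists held 1098 genes, of which 1084 were measured.

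Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 signals of all 9 arrays, with group means, default empirical Bayes settings and Benjamini-Hochberg adjustment. The residual degrees of freedom were 6 and the prior degrees of freedom 3.34. A gene was called at an adjusted p under 0.05. The diet comparison was Lrat-/- deficient minus Lrat-/- sufficient, the genotype comparison was Lrat-/- sufficient minus wild type, and the combined comparison was Lrat-/- deficient minus wild type. A moderated F test asked whether any group differed. A set of 44 gene lists was tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were also run. Members of a list were counted both from the adjustment over all genes and when adjusted over the list alone. The adjustment over the list alone was made separately in each of the 44 lists and each comparison. It was not corrected across them, so some members can pass it by chance. Lrat was also compared between 3 wild-type and 6 Lrat-/- arrays by an exact permutation test in scipy 1.17.1 under Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

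The rule for named genes took up to 10 called genes per direction with the largest change whose groups did not overlap, then filled each direction to 5 by the lowest unadjusted p. It added Lrat, each called member of a list, and the 4 members with the lowest unadjusted p of each list past the threshold. Predicted genes, RIKEN clones and olfactory receptors were counted and not named, and some genes the rule picks are not reported here. The comparisons, tests, lists, naming rule and other settings were fixed before the data were examined. Genes named outside the rule were chosen after their values were seen, and so was the comparison of all 6 Lrat-/- arrays with the wild type.

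The samples carry the numbers 1 to 3 in every group. After the group means were removed, all 9 same-number pairs were positively correlated, with r across genes between 0.138 and 0.391, against -0.365 to 0.223 for pairs with other numbers. The numbers therefore go with a shared structure in these data, although no label says what they share. Part of it may come from the arrays numbered 3 alone, so a pairing of the numbers 1 and 2 is less certain. Wild-type array 1 correlated more with deficient array 2 (0.223) than with deficient array 1 (0.138). In 7 of 9 arrays the correlation was highest with the same number in both other groups. The replicate number as a block was one of the other settings. The arrays numbered 3 also stood apart on the first principal component. Of 81 fittable ways to choose 3 of the 9 arrays as a scan batch, taking the arrays numbered 3 came nearest to the authors' residual sums of squares, with a median absolute log2 ratio of 0.484 against 0.630 for the next. The arrays numbered 3 were therefore treated as a possible scan batch, a setting chosen after the data were seen.

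The gene test was checked on simulated data for the genotype comparison, with 22060 genes and 20 draws. It recovered 48.5% of genes changed by 0.5 on the log2 scale, 96.1% of those changed by 1 and 99.8% of those changed by 2, with 8.55 false calls per draw. Each draw held 67, 67 and 66 genes changed by these sizes. With fewer changed genes the adjusted threshold is harder to pass, so these shares are not the power of the real comparisons. The list test found a simulated shift of 0.25 in the calcium handling list in 20 of 20 draws of the diet comparison, with 0.05 other lists called per draw. The noise was drawn independently for each gene and array, without the correlation between genes that real lists can have. The list rates therefore do not carry over to the real lists.

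The other settings were a fit of the 2 compared groups alone, a filter on genes under the 40th percentile of mean signal, every probe set, median centring, a second quantile normalization, a trended and robust variance model, array weights, the replicate block, an adjusted p under 0.1, and leaving out each array in turn. Using other value columns in place of the series table was planned and not run, because those columns match no sample label.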

Results

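Expression in the right ventricle was measured in 3 groups of 3 male mouse samples that differed in genotype and in dietary vitamin A. Lrat encodes lecithin-retinol acyltransferase, the enzyme that esterifies retinol for storage, so Lrat-/- mice lack the main retinoid store. The sufficient diet held 250000 U/kg of retinol palmitate, the deficient diet held none added, and the mice were killed after 50 days. The median log2 signal of the 22060 genes lay between 7.16 and 7.21 in each array, and r between any 2 arrays was 0.987 to 0.998. The first principal component, with 28.4% of the variance, set the arrays numbered 3 apart from the others in every group, and the second held 22.1%.

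**Figure D1:**
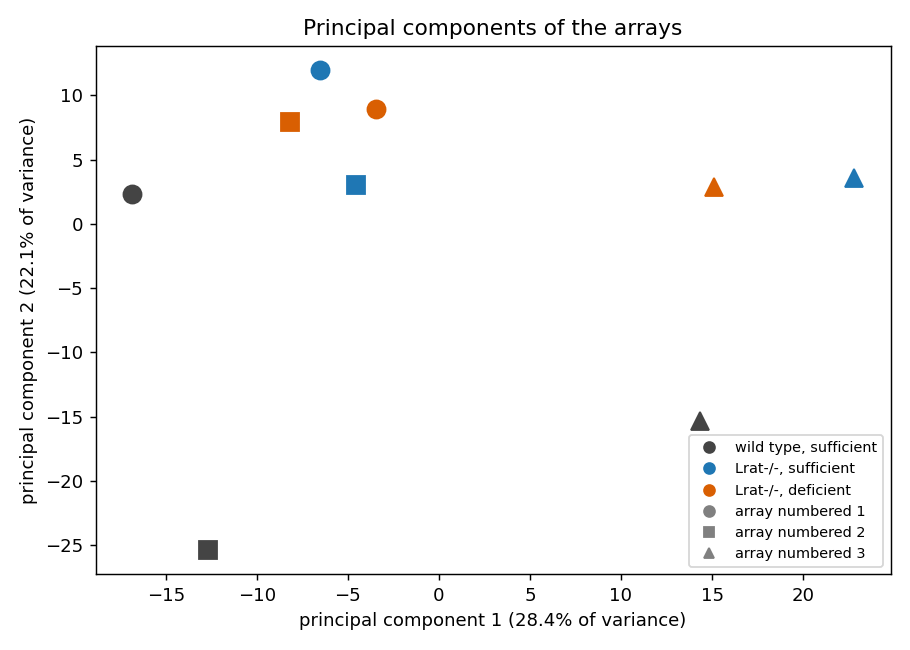
Scores of the 9 arrays on the first 2 principal components of the log2 signals of all genes (28.4% and 22.1% of the variance), coloured by group and shaped by array number. The arrays numbered 3 lie between 14.3 and 22.8 on the first component and the other arrays between -16.9 and -3.46.

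The targeted gene was examined first as a check of the labels. Lrat signal was higher, not lower, in the arrays labelled Lrat-/-. Its log2 signal was 6.34 ± 0.09 in wild type (SD, n = 3), 7.87 ± 0.22 in arrays labelled Lrat-/- on the sufficient diet and 7.69 ± 0.12 on the deficient diet. All 6 arrays labelled Lrat-/-, from 7.58 to 8.09, lay above all 3 wild-type arrays, from 6.24 to 6.43, with a mean difference of 1.44 (exact permutation test, two-sided p = 0.0238 over 84 splits, the smallest p this test can give). In the authors' deposited table the Lrat ratio to wild type was 3.04 on the sufficient and 2.61 on the deficient diet. A probe set outside the deleted part of the gene checks nothing, and the position of this one relative to the deletion is not known here. The groups are therefore named by their labels, and each direction drawn from the genotype rests on those labels.

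The genotype comparison asks what differs in the right ventricle of mice labelled Lrat-/- when vitamin A is supplied. Gdpd3, a phosphodiesterase that acts on lysophospholipids, fell by 4.88 on the log2 scale in arrays labelled Lrat-/-, from 10.73 ± 0.37 to 5.84 ± 0.13 (SD, n = 3, adjusted p = 6.12e-06). Hal, the first enzyme of histidine breakdown, fell 5.25-fold (adjusted p = 0.00604), and Plekha7, an adherens junction protein, 2.34-fold (adjusted p = 0.00334). Elovl7, a fatty acid elongase, fell from 7.25 ± 0.29 to 5.52 ± 0.12 (SD, n = 3, adjusted p = 0.00153). The background controls of those arrays averaged 5.60, so Elovl7 was no longer above background and Gdpd3 and Hal lay only 0.24 and 0.47 above it, and the size of these falls is not known exactly. Lgr6, a receptor for R-spondins, rose by 1.63 on the log2 scale, from 7.71 ± 0.32 to 9.34 ± 0.04 (SD, n = 3, adjusted p = 0.00245). Pkig, an inhibitor of protein kinase A, rose 2.22-fold (adjusted p = 0.00842), and the Lrat probe set rose 2.89-fold (log2 1.53, SE 0.12, adjusted p = 0.00153). The olfactory receptor gene Olfr872, named after its values were seen, completed the 5 genes that fell, from 5.66 to 3.51, and its wild-type signal was itself only 0.19 above background. No other gene passed: Cdc14b, a phosphatase, had a log2 change of 1.07 (adjusted p = 0.0806, and 0.0184 with the replicate number as a block) and the potassium channel Kcnj14 -0.84 (adjusted p = 0.0540).

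**Figure D2:**
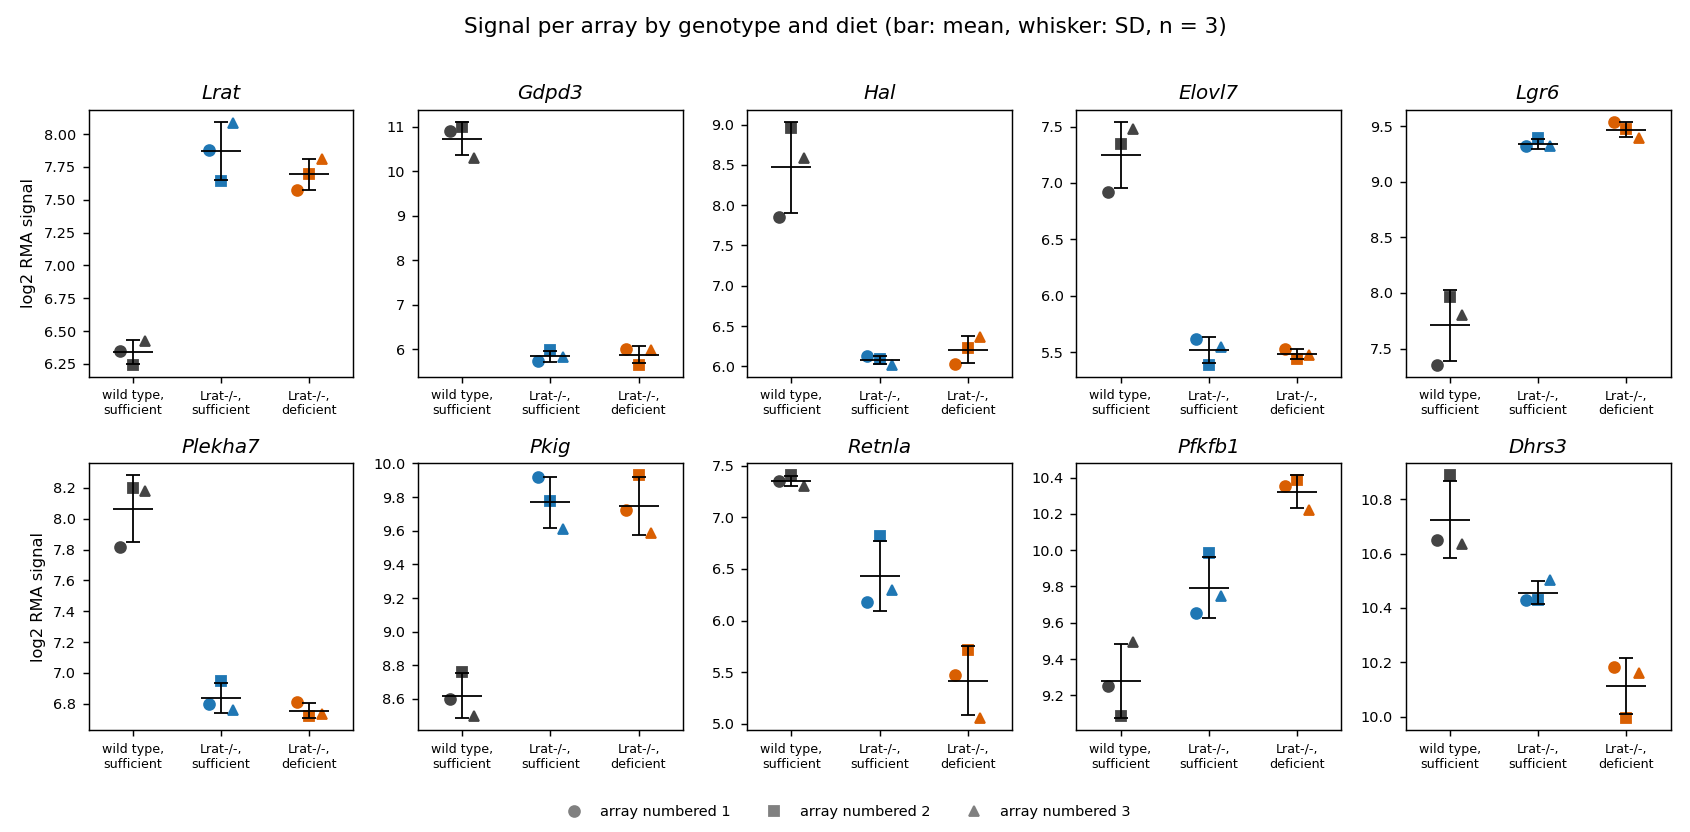
Log2 RMA signal of 10 genes in each array, by labelled genotype and diet. Points are arrays, shaped by their number, with the group mean (bar) and SD (whisker, n = 3). Lrat lies between 7.58 and 8.09 in the arrays labelled Lrat-/- and between 6.24 and 6.43 in wild type, and Gdpd3 averages 10.73 in wild type and 5.84 in arrays labelled Lrat-/- on the sufficient diet.

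Genes of the connective tissue lay lower together in arrays labelled Lrat-/-. Of 48 extracellular matrix genes, 42 were lower (mean log2 difference -0.21, camera adjusted p = 4.32e-13, but adjusted p = 0.252 with an estimated correlation), and of 23 fibroblast markers 22 were lower (-0.22, 2.20e-10, but adjusted p = 0.252 with an estimated correlation). The mean of the fibroblast markers was -0.08 ± 0.03 around the overall average in arrays labelled Lrat-/- and 0.15 ± 0.06 in wild type (SD, n = 3). None of these genes passed over all genes. Adjusted over the list alone, 1 matrix gene and 1 fibroblast marker fell: the proteoglycan Bgn (log2 -0.44) and the microfibril protein Mfap4 (-0.51). Not past either threshold were Mmp2 (-0.44), Ccn2 (-0.58), Fmod (-0.86), Pi16 (-0.60), Fbln1 (-0.40) and Col1a1 (-0.27). Of 23 mesothelial markers, 21 were lower (-0.25, adjusted p = 1.97e-06, but adjusted p = 0.292 with an estimated correlation), among them Msln (-0.48), Clu (-0.34), C3 (-0.47) and Upk1b (-0.57), and without wild-type array 1 the difference was -0.16 and still called.

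Genes of antigen presentation and other immune lists were also lower. All 26 antigen presentation genes were lower (mean log2 difference -0.44, adjusted p = 3.47e-17, but adjusted p = 0.373 with an estimated correlation). None passed over all genes, and 11 fell when adjusted over the list alone, including H2-T24 (-0.77), H2-Q6 (-1.60), H2-K1 (-0.83) and H2-Q4 (-0.97). Of 41 interferon response genes, 31 were lower (-0.23, adjusted p = 6.11e-05, but adjusted p = 0.613 with an estimated correlation), with Gbp6 at -0.84, Gbp4 at -0.90 and Tgtp1 at -1.18 but Ifi204 at 0.31, none past the threshold. Wild-type array 2 was high for both lists, with an antigen presentation mean of 0.56 against -0.06 and 0.27 in the other wild-type arrays. Without it the interferon difference was -0.08 and the call ended (adjusted p = 0.267), and the antigen presentation difference was -0.29, still called but smaller than the -0.32 of the mesothelial list in the same fit. Macrophage markers (22 of 26 lower, -0.15, adjusted p = 0.000345, but adjusted p = 0.394 with an estimated correlation) included Mpeg1 (-0.39), Adgre1 (-0.40), Lyz1 (-0.47) and Csf1r (-0.25), and without wild-type array 2 the difference was -0.07 and not called (adjusted p = 0.129). Complement genes (16 of 19 lower, -0.17, adjusted p = 0.00260, but adjusted p = 0.394 with an estimated correlation) included C4b (-0.85), C3 and Serping1 (-0.32), with Cd59a at 0.60. Cytokine genes (28 of 41 lower, -0.09, adjusted p = 0.0131, but adjusted p = 0.252 with an estimated correlation) included Il18 (-0.20), Ccl6 (-0.35), Icam1 (-0.26) and Cxcl13 (-0.47), and without wild-type array 2 the list was not called (adjusted p = 0.150). No member of these 3 lists passed any threshold.

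Lists of immediate early, lipid, muscle and erythrocyte genes were also called. Immediate early genes were lower in 23 of 26 (mean log2 difference -0.29, adjusted p = 1.05e-06, but adjusted p = 0.430 with an estimated correlation), with Arc at -1.14, Ccn1 at -0.56, Btg2 at -0.43 and Junb at -0.27. Most of this came from wild-type array 2, with a mean of 0.58 against -0.02 and 0.04 in the other wild-type arrays, and without it the difference was -0.10 and not called (adjusted p = 0.0836). Cholesterol and lipid synthesis genes were lower in 21 of 29 (-0.12, adjusted p = 0.000345, but adjusted p = 0.394 with an estimated correlation), with Scd1 at -0.58, Fasn at -0.32, Srebf1 at -0.28 and Fdft1 at -0.16, and without wild-type array 1 the difference was -0.08 and still called (adjusted p = 0.0458). Calcium handling genes were higher in 21 of 27 (0.11, adjusted p = 0.0120, but adjusted p = 0.394 with an estimated correlation). Casq1, a calcium store protein of the sarcoplasmic reticulum, rose by 1.05 when adjusted over the list alone (adjusted p = 0.00502) and was not past the threshold over all genes. Slc8a1 had 0.26, Itpr1 0.19 and S100a1 -0.41. The calcium list was not called without wild-type array 2 or without array 1 or 2 of the group labelled Lrat-/- (highest adjusted p = 0.124), with at least 77.9% of the difference kept, and the difference was 0.15 in the arrays numbered 1 and 2 and 0.02 in those numbered 3. Ion channel genes were higher in 22 of 33 (0.07, adjusted p = 0.0116, but adjusted p = 0.430 with an estimated correlation). The potassium channel genes Kcnj11 (0.39) and Kcnq1 (0.31) rose when adjusted over the list alone, and the calcium channel gene Cacna1h had 0.40. The ion channel list was not called without wild-type array 1 (adjusted p = 0.161), with 55.5% of the difference kept, or without array 1 of the group labelled Lrat-/-. Erythrocyte markers were higher in 13 of 14 (0.15, adjusted p = 0.0119, but adjusted p = 0.513 with an estimated correlation), with Slc4a1 at 0.35, Slc25a37 at 0.18, Mkrn1 at 0.12 and Alas2 at 0.28. Without wild-type array 3 the erythrocyte difference was 0.08 and not called (adjusted p = 0.318), and the list was not called without array 1 of the group labelled Lrat-/- (adjusted p = 0.0641).

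In all, limma called 8 genes in the genotype comparison, 3 higher and 5 lower, with 1261 genes at an unadjusted p under 0.05 (1846 with the replicate number as a block) against 1103 expected with no change, and camera called 13 of the 44 lists. None of the 13 was called with an estimated correlation, and 7 lost the call when 1 array was left out. The 3 arrays of each group did not overlap for 7.70% of genes, against 10% by chance. All 8 genes and all 13 lists had the same sign within the arrays numbered 1 and 2 and within those numbered 3, and all 8 genes stayed past the threshold with the arrays numbered 3 as a block, which leaves the differences themselves unchanged. Without the arrays numbered 3, in a fit with fewer samples, 2 genes were called, and of the 8 only Gdpd3 was among them. The others kept differences of a similar size there: Elovl7 -1.63, Hal -2.30, Plekha7 -1.13, Olfr872 -2.21, Lgr6 1.69, Lrat 1.47 and Pkig 1.16. The cytokine, complement and interferon lists were no longer called in that fit (adjusted p = 0.0907, 0.119 and 0.0778), where their differences were -0.09, -0.15 and -0.19. Hal was not past the threshold without array 3 of the group labelled Lrat-/- on the sufficient diet (adjusted p = 0.0642), and Pkig was not without array 1 or array 2 of that group (highest adjusted p = 0.0648).

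The diet comparison asks what vitamin A deficiency changed within the genotype labelled Lrat-/-. No single gene passed the threshold. The largest signals by unadjusted p were Klf10, a transcription factor induced by TGF-beta (log2 -0.72, SE 0.12), Retnla, a secreted protein of alternatively activated macrophages (-1.02, SE 0.19), and Mki67, a proliferation marker (0.52, SE 0.11), each with an adjusted p of 1. The Retnla signal was on average not above background in the deficient arrays, so the size of its change is not known exactly. Pfkfb1, an enzyme that sets the level of fructose 2,6-bisphosphate, had 0.53. Of the others named by the rule, Gem had 0.34, Ms4a14 0.39, Prnd 0.46, Rtn4r -0.46 and the smooth muscle actin gene Acta2 -1.10. Acta2 fell when adjusted over the 18 smooth muscle and pericyte markers alone (adjusted p = 0.0270). In the genotype comparison, which uses the same sufficient-diet arrays with the opposite sign, it rose by 1.07 on that adjustment (adjusted p = 0.0311). The SD of its log2 signal among those 3 arrays was 0.54.

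Camera with its preset correlation called 7 lists in the diet comparison, each with a small mean difference. Each of these 7 lists had adjusted p = 0.711 with an estimated correlation, and none of their members passed over all genes or over its list alone. Interferon response genes were higher in 35 of 41 (mean log2 difference 0.16, adjusted p = 2.55e-06), with Mx2 at 0.31, Iigp1 at 0.63, Rtp4 at 0.38 and Irgm2 at 0.59. Antigen presentation genes were higher in 23 of 26 (0.12, adjusted p = 0.00103), with H2-Q6 at 0.57, H2-Q4 at 0.40, H2-Ab1 at 0.27 and B2m at 0.18. Oxidative phosphorylation genes were higher in 39 of 46 (0.10, adjusted p = 3.86e-06), with Ndufa4 at 0.46, Cox7b at 0.34, Uqcrb at 0.19 and Ndufs3 at 0.13. Fatty acid oxidation genes were higher in 29 of 38 (0.05, adjusted p = 0.00391), with Ucp3 at 0.26, Acot1 at 0.27, Acaa2 at 0.10 and Acot2 at 0.11. Mesothelial markers were lower in 22 of 23 (-0.14, adjusted p = 0.000974), with Upk3b at -0.65, Upk1b at -0.42, Efemp1 at -0.26 and Krt18 at -0.20. Endothelial markers were higher in 19 of 26 (0.07, adjusted p = 0.00179), with Cdh5 at 0.24, Pecam1 at 0.18, Esam at 0.13 and Aqp1 at -0.42. Cell cycle genes were higher in 27 of 44 (0.06, adjusted p = 0.00179), with Mki67, Prc1 at 0.34, Ube2c at 0.30 and Bub1 at 0.32.

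In all, limma called 0 genes in the diet comparison, with 290 at an unadjusted p under 0.05 (533 with the replicate number as a block) against 1103 expected with no change, and 0 with the replicate number as a block. With array weights it called 2, the cytokine gene Ccl6 (log2 -0.73, adjusted p = 0.0492) and 1700031F05Rik (-0.43, the same adjusted p), both named after their values were seen. The arrays did not overlap for 5.22% of genes, against 10% by chance. This share and the number of small p-values both lie under what no change would give, so the diet test appears conservative. The 0 calls therefore do not show that diet changed nothing. When 1 array was left out, the lists for fatty acid oxidation (highest adjusted p = 0.252), antigen presentation (0.294), endothelial markers (0.111), mesothelial markers (0.103) and the cell cycle (0.0707) lost the call. In that order, as little as 32.5%, 52.6%, 45.5%, 67.5% and 67.0% of the difference was kept. The lists for interferon and oxidative phosphorylation kept the call, with as little as 62.8% of the difference without array 3 of the sufficient group and 56.0% without array 3 of the deficient group. Of the 10 ways to split these 6 arrays into 3 and 3, 3, the real one among them, gave at least 7 lists, so the number of lists is not set apart from chance. All 7 lists had the same sign within the arrays numbered 1 and 2 and within those numbered 3. The oxidative phosphorylation shift was 0.05 in the arrays numbered 1 and 2 and 0.20 in those numbered 3, and the fatty acid oxidation shift was 0.06 and 0.02. Without the arrays numbered 3 the antigen presentation and endothelial lists were no longer called (adjusted p = 0.134 and 0.0699), with differences of 0.10 and 0.06.

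The combined comparison asks what differs when the genotype label and the deficient diet come together. The genes of the genotype comparison recurred: Gdpd3 (log2 -4.85, adjusted p = 6.56e-06), Elovl7 and Hal (adjusted p = 0.00846) fell to or near background, and Plekha7 fell 2.48-fold, while Lgr6 rose 3.39-fold, Lrat 2.56-fold and Pkig 2.18-fold. Retnla fell from 7.35 ± 0.05 in wild type to 5.42 ± 0.33 in deficient arrays labelled Lrat-/- (SD, n = 3, adjusted p = 0.00749), with 6.43 ± 0.34 on the sufficient diet. The deficient arrays had background controls at 5.64 on average, above that mean Retnla signal. Pfkfb1 rose 2.06-fold, from 9.28 ± 0.20 to 10.32 ± 0.09 (adjusted p = 0.0204), with 9.79 ± 0.17 on the sufficient diet, and was the only called gene of the 36 in the glucose list. The other genes that rose were Rsph3a, a radial spoke protein (log2 0.99, adjusted p = 0.0495), Tmc7 (0.82, adjusted p = 0.0288), the small GTPase Rerg (0.73, adjusted p = 0.0455, but 0.0588 with the replicate number as a block), the actin-binding Limch1 (0.64, adjusted p = 0.0495) and the D-glutamate cyclase Dglucy (0.62, adjusted p = 0.0264). Olfr872 also fell, to 3.48.

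Retinoid genes were examined as 2 fixed lists. Of 36 genes of retinoid metabolism, Lrat was the only one called over all genes, in the genotype and the combined comparisons. Adjusted over the list alone, the combined comparison had 2 higher and 2 lower: Lrat and the retinol-binding protein gene Rbp7 (log2 1.12) rose, and the retinaldehyde reductase gene Dhrs3 (-0.61) and the retinoic acid hydroxylase gene Cyp26b1 (-0.38) fell. These 3 genes were named after their values were seen, and over all genes their adjusted p-values were 0.315, 0.0754 and 0.224. Dhrs3 had -0.27 in the genotype and -0.34 in the diet comparison, where it did not pass. As a set, the metabolism list did not pass (camera adjusted p = 0.160 for diet, with 26 of 36 lower, 0.629 for genotype and 0.688 for combined, where the mean was 0.01 and the median -0.01). Nor did the 41 retinoic acid receptors and targets (0.0941 for diet, with 30 of 41 lower, 0.539 for genotype, where the median was -0.02 and the mean 0.00, and 0.0892 for combined). Lrat itself is a member of both lists, so its rise (log2 1.53 for genotype and 1.35 for combined) enters their means. Neither list was tested without it.

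Connective tissue and immune lists were again lower in deficient arrays labelled Lrat-/- than in wild type. Mesothelial markers were lower in 22 of 23 (mean log2 difference -0.39, adjusted p = 1.47e-12, but adjusted p = 0.217 with an estimated correlation). Adjusted over the list alone 6 of them fell, including Upk3b (-1.36), Upk1b (-0.99), Msln (-0.68) and Clu (-0.43). Matrix genes were lower in 43 of 48 (-0.21, adjusted p = 1.48e-12, but adjusted p = 0.217 with an estimated correlation), with 6 that fell over the list alone, including Fmod (-0.94), Ccn2 (-0.69), Col14a1 (-0.45) and Bgn (-0.33). Fibroblast markers were lower in 21 of 23 (-0.22, adjusted p = 5.24e-08, but adjusted p = 0.217 with an estimated correlation). Pi16 (-0.86) and Mfap4 (-0.46) fell over the list alone, with Fbln1 at -0.37 and Medag at -0.40. Antigen presentation genes were lower in 26 of 26 (-0.32, adjusted p = 8.81e-10, but adjusted p = 0.361 with an estimated correlation), of which H2-T24 (-0.71) fell over the list alone, with H2-Q6 at -1.03, H2-K1 at -0.64 and Psmb8 at -0.35, and without wild-type array 2 the difference was -0.17 and still called. Macrophage markers (23 of 26 lower, -0.16, adjusted p = 0.000199, but adjusted p = 0.294 with an estimated correlation) included Lyve1 (-0.58), Lyz1 (-0.46), Folr2 (-0.27) and Itgam (-0.30), and without wild-type array 2 the difference was -0.08 and not called (adjusted p = 0.0873). Complement genes (17 of 19 lower, -0.21, adjusted p = 0.000407, but adjusted p = 0.265 with an estimated correlation) included C4b (-0.73), C3 (-0.48) and Serping1 (-0.28), with Cd59a at 0.56. Cytokine genes (29 of 41 lower, -0.09, adjusted p = 0.0230, but adjusted p = 0.217 with an estimated correlation) included Ccl6, which fell by 0.93 over the list alone, with Tnf at -0.28, Cxcl2 at -0.17 and Lcn2 at 0.65.

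**Figure D3:**
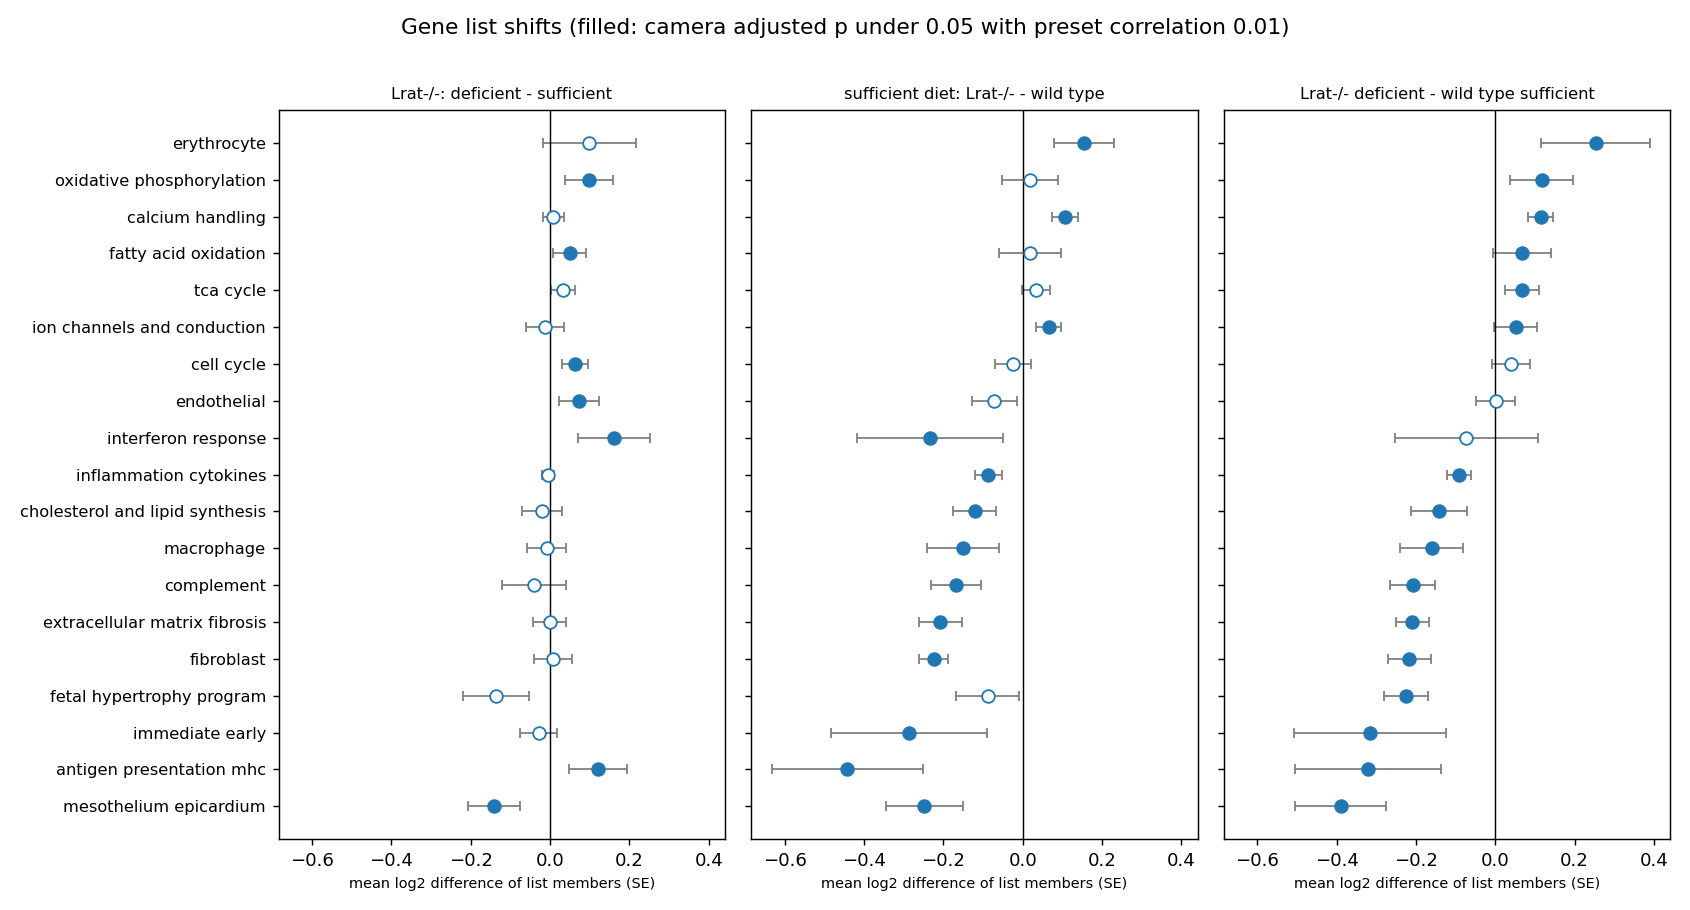
Mean log2 difference of the members of each list past the threshold in at least 1 comparison, with the SE over arrays, for the diet, genotype and combined comparisons. Filled points passed camera with its preset correlation of 0.01, and none passed with an estimated correlation. Matrix genes lie at -0.21 in the genotype and the combined comparison, and interferon genes at 0.16 with diet and -0.23 with genotype.

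The mean of the fetal cardiac and stress programme was lower, and the means of energy and calcium lists were higher, in the combined comparison. The fetal programme was lower in 17 of 24 (mean log2 difference -0.22, adjusted p = 0.00571, but adjusted p = 0.217 with an estimated correlation). Over the list alone 4 of its genes fell: the natriuretic peptide genes Nppb (-1.60) and Nppa (-1.34), skeletal actin Acta1 (-1.20) and Ccn2 (-0.69). These 4 genes carried most of the list's mean difference. The list's shift was -0.30 in the arrays numbered 1 and 2 and -0.08 in those numbered 3. Immediate early genes were lower in 25 of 26 (-0.32, adjusted p = 3.95e-07, but adjusted p = 0.361 with an estimated correlation), with Nr4a1 at -1.14, Nr4a3 at -0.80, Btg2 at -0.43 and Klf4 at -0.37. Without wild-type array 2 the immediate early difference was -0.13, 39.6% of its size, and still called (adjusted p = 0.0213). The immediate early shift was -0.41 in the arrays numbered 1 and 2 and -0.14 in those numbered 3. Cholesterol and lipid synthesis genes were lower in 25 of 29 (-0.14, adjusted p = 4.15e-05, but adjusted p = 0.265 with an estimated correlation), and Scd1 (-0.62) fell over the list alone, with Me1 at -0.28 and Srebf1 at -0.28. Oxidative phosphorylation genes were higher in 37 of 46 (0.12, adjusted p = 2.03e-05, but adjusted p = 0.401 with an estimated correlation), with Ndufs4 at 0.56, Uqcrb at 0.41, Ndufa4 at 0.40 and Atp5j at 0.18. Fatty acid oxidation genes (28 of 38 higher, 0.07, adjusted p = 0.000255, but adjusted p = 0.421 with an estimated correlation) included Ppara (0.24), Ppargc1a (0.23) and Etfdh (0.17). Citric acid cycle genes (16 of 19 higher, 0.07, adjusted p = 0.0150, but adjusted p = 0.421 with an estimated correlation) included Suclg1 (0.20), Dld (0.19), Fh1 (0.17) and Idh3b (0.11). Calcium handling genes (20 of 27 higher, 0.11, adjusted p = 0.000461, but adjusted p = 0.249 with an estimated correlation) included Casq1 (0.69), Cacna2d1 (0.49), Hrc (0.35) and Itpr1 (0.22). The calcium handling shift was 0.15 in the arrays numbered 1 and 2 and 0.04 in those numbered 3. Ion channel genes (18 of 33 higher, 0.05, adjusted p = 0.00485, but adjusted p = 0.363 with an estimated correlation) had 3 that rose over the list alone, Kcnj3 (0.39), Kcnj11 (0.37) and Kcnq1 (0.33), and 2 that fell, Kcne1 (-0.78) and Kcnip2 (-0.38, named after its value was seen). Erythrocyte markers were higher in 12 of 14 (0.25, adjusted p = 2.75e-05, but adjusted p = 0.293 with an estimated correlation), with Hbb-b1 at 0.65, Alas2 at 0.55 and Slc4a1 at 0.47, and without array 3 of the deficient group the difference was 0.15 and still called.

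In all, limma called 15 genes in the combined comparison, 9 higher and 6 lower, with 1344 at an unadjusted p under 0.05 (1884 with the replicate number as a block), and camera called 16 lists, none of them with an estimated correlation. When 1 array was left out 6 of the 16 lost the call: citric acid cycle (highest adjusted p = 0.348), cytokines (0.170), oxidative phosphorylation (0.169), ion channels (0.0991), macrophages (0.0873) and fatty acid oxidation (0.0744). In that order, their differences kept as little as 54.7%, 67.6%, 52.7%, 40.9%, 51.5% and 43.8% of their size. The arrays did not overlap for 8.16% of genes, against 10% by chance. All 15 genes had the same sign within the arrays numbered 1 and 2 and within those numbered 3, and all 15 stayed past the threshold with the arrays numbered 3 as a block. Without the arrays numbered 3, in a fit with fewer samples, 3 genes were called, of the 15 only Gdpd3. There Retnla still had -1.78, Pfkfb1 1.20, Rsph3a 0.91, Tmc7 0.95, Rerg 0.64, Limch1 0.67 and Dglucy 0.57. Of the genes shared with the genotype comparison, Elovl7 had -1.65, Hal -2.28, Plekha7 -1.24, Olfr872 -2.20, Lgr6 1.84, Lrat 1.34 and Pkig 1.14. The oxidative phosphorylation shift was 0.02 in the arrays numbered 1 and 2 and 0.31 in those numbered 3, and the erythrocyte shift was 0.07 and 0.61. Neither list was called without the arrays numbered 3 (adjusted p = 0.371 and 0.123), nor was the cytokine list (0.130, with a difference of -0.10), and the ion channel shift was -0.07 within the arrays numbered 3. Retnla was not past the threshold without array 1 of the deficient group (adjusted p = 0.0537), Hal was not without any 1 of that group's arrays (highest adjusted p = 0.0822) and Pkig was not without its array 1 or 2 (highest adjusted p = 0.0695). Dglucy, Limch1, Pfkfb1, Rerg, Rsph3a and Tmc7 each lost the call when 1 array was left out, in 6 to 8 of the 9 cases.

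Of the 15 genes called in the combined comparison, 8 were also called in the genotype comparison, all in the same direction, against 0.00122 higher and 0.00136 lower expected of independent lists. These comparisons share the wild-type arrays. Across genes, r between their log2 changes was 0.78, against 0.50 for simulated unchanged groups, and the covariance exceeded the simulated one by 0.0156. The simulation gave each gene the same spread in every group. A wider spread among the wild-type arrays would make its covariance too low a reference. The wild-type arrays were too few to split, so part of the excess may come from the shared arrays. No gene was called in both the diet and the genotype comparison. There r was -0.31, against -0.50 for simulated unchanged groups that share the sufficient-diet arrays with opposite sign, and the covariances differed by 2.13e-05. For diet and combined, which share the deficient arrays, r was 0.35 against 0.50, with a covariance difference of 0.000604. The F test over the 3 groups called 9 genes.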

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

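The comparison of all 6 arrays labelled Lrat-/- with the 3 wild-type arrays, and the tests of a mislabelled sample, of less non-muscle tissue, of differences carried by the arrays numbered 3 and of retinoid supply in genes above background, were chosen only after the results were seen.

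Probe sets outside the gene test, which were given no gene name here or are array controls, numbered 10092, and among them 6 were higher and 2 lower in both groups labelled Lrat-/- than in wild type. Of the distinct signals that were higher, probe set 10415081, described in the files as an endogenous virus of the spleen focus-forming type, was higher by 5.95 on the log2 scale on the sufficient diet (5.45 ± 0.43 in wild type, 11.40 ± 0.11 in arrays labelled Lrat-/-, SD, n = 3, limma adjusted p = 6.74e-06). Its values were identical in 4 probe sets. Probe set 10468877, which has no description, was higher by 5.20 (5.76 ± 0.21 against 10.96 ± 0.06, limma adjusted p = 7.27e-07). Probe set 10338859, an array control made to give background signal, was higher by 2.82 (4.83 ± 0.15 against 7.64 ± 0.27, limma adjusted p = 0.000118). In wild type these 3 signals lay at, near or under the background controls, which averaged 5.48 there, so the sizes of the differences are not known exactly. The probe sets that were lower were 10343587, an array control made to give signal (11.42 ± 0.14 in wild type, 9.61 ± 0.29 on the sufficient diet), and 10489782, described as a pseudogene (8.22 ± 0.54 and 5.64 ± 0.22, the latter near background).

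The higher Lrat signal in arrays labelled Lrat-/- is the first pattern. A single mislabelled sample is argued against by the gap of 1.15 between the lowest array labelled Lrat-/- and the highest wild-type array, against a largest range of 0.44 within a group. Wrong labels on whole groups could leave the same gap, so it does not test them. A change shared with the neighbouring genes is argued against because 1 of the 20 nearest measured genes, Sfrp2, had an unadjusted p under 0.01. A transcript altered by the targeting that the probe set still reads may account for the signal, but the position of the probe set is not known here, and this stays untested.

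The genes that differ between arrays labelled Lrat-/- and wild type, 19 in the comparison of all 6 arrays with 3, are the second pattern. Whether the arrays numbered 3 carry these differences cannot be told for the 19 genes, which were chosen on all arrays. In the arrays numbered 1 and 2 alone each kept between 83.8% and 118% of its difference, with a median of 101.5%. The differences were thus present there too. Genes called for a small spread within groups would keep most of their difference in any case, so these shares do not decide it. Only Gdpd3 and Olfr872, 2 of the 19, were called there, in a fit with fewer samples. The block, with which 19 of 19 kept the call, leaves every difference unchanged and so does not test this. Retinoid supply graded by diet cannot be told apart with these few genes: over the 14 that do not fall to within 0.5 of background, the median diet change in the same direction was 0.075, and that less the 0.213 set as the least it would need was -0.14 (bootstrap 95% interval -0.31 to 0.04). A segment of another strain around Lrat may contribute and cannot be told apart from chance with these few genes: 6 of 200 flanking genes (3%) and 478 of 21098 others (2.27%) had an unadjusted p under 0.01, a ratio of 1.32 (95% interval of the odds ratio 0.481 to 2.98, Fisher's exact test, two-sided p = 0.468). An effect of the labelled genotype at a constant retinoid supply, and a difference of strain elsewhere, stay open.

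The lower connective tissue lists in arrays labelled Lrat-/- are the third pattern. The possible scan batch, the arrays numbered 3, is argued against as the carrier of the matrix difference. Without those arrays the matrix list kept 92.9% of its mean difference in one group and 99.2% in the other. Each group holds an array numbered 3, so a shift common to that batch cancels from these differences and is not tested here. A single wild-type array is argued against, because the matrix list kept at least 83.3% of its difference whichever one was left out, although the mesothelial list kept 63.4% in the genotype comparison without wild-type array 1 and so rests on that array in part. Less non-muscle tissue of every kind is argued against only as far as endothelial and smooth muscle markers go. The median change of 23 fibroblast markers lay 0.20 below that of these 44 markers (-0.20, bootstrap 95% interval -0.28 to -0.10), whose own median was -0.007. The bootstrap drew genes and not arrays, so its interval leaves out the spread between samples. Fewer fibroblasts, or less matrix expression in each, may both be involved and were not told apart, and with an estimated correlation 0 of these lists were called.

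Other splits of the same arrays were counted for each result. For 6 arrays against 3, fitted as 2 groups, 2 of the 84 splits, the real one among them, gave as many genes as the real one, a share under 0.05. This makes chance less likely and does not exclude it, since the comparison was chosen after the results were seen. The real split gave 19 genes and the highest other 1048. That other split set the arrays numbered 3 against the rest, which points to a structure of the samples. With the arrays numbered 3 as a block the comparison called 38 genes, and of the 27 splits that part all 3 pairs of numbers the highest other gave 0. For the F test over 3 groups chance is not excluded: 8 of 100 drawn splits gave as many as the real 9, the highest other 69, and of the 10 drawn that part all the numbers the highest other gave 9. Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. There the real genotype comparison gave 8 genes and the highest other 0 (1 of 10 gave as many), the combined 15 and 0 (1 of 10), and the diet 0 and 0 (10 of 10). For lists the real genotype comparison gave 13 and the highest other 13 (2 of 10 gave as many), the combined 16 and 13 (1 of 10), and the diet 7 and 8 (3 of 10). Among the 4 of those splits that part all 3 pairs, the highest other gave 0 genes in each comparison, and 9, 10 and 8 lists for genotype, combined and diet.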

How the results depend on the processing

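The settings that treat the arrays numbered 3 as a block or leave them out, and the comparison of all 6 arrays labelled Lrat-/- with wild type, were chosen after the data were seen. No result reversed under any setting that was run. Gdpd3, Lrat, Elovl7, Lgr6 and Plekha7 stayed past the threshold whichever single array was left out. Of the results for named genes, 1841 kept their side of the threshold under the settings that keep every array or leave out the arrays numbered 3, 38 fell short of it and 9 newly passed. Using other value columns was planned and not run.

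With only the 2 compared groups in the fit, which has fewer degrees of freedom, 2 genes were called for genotype and 9 for combined, and Lrat kept its genotype change of 1.53 with an adjusted p of 0.0666. Testing every probe set called 15 for genotype and 16 in any group. Array weights called 2 for diet, 32 for combined and 26 in any group, and the cause was not tested. An adjusted p under 0.1, a looser threshold, called 16 for genotype and 15 in any group. Leaving out the arrays numbered 3, which has fewer samples, called 2 genes for genotype, 3 for combined, 2 in any group and 11 lists for diet. Lrat was then no longer past the threshold, with 1.47 for genotype (adjusted p = 0.110) and 1.34 for combined (adjusted p = 0.0743). Lrat kept its combined call with only the 2 compared groups in the fit (adjusted p = 0.0139), and kept both calls under the remaining settings, with an adjusted p up to 0.0308 when 1 array was left out.

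Camera with an estimated correlation called 0 lists for diet, 0 for genotype and 0 for combined, and fry also called 0, 0 and 0, so the 36 list calls rest on the small preset correlation. Under the settings other than leaving out 1 array, 241 list calls were kept and 83 lost, and with 1 array left out 293 were kept and 31 lost. Without wild-type array 2 the genotype lists for interferon (adjusted p = 0.267), cytokines (0.150), macrophages (0.129), immediate early genes (0.0836) and calcium handling (0.0836) were not called. Without wild-type array 3 the combined lists for oxidative phosphorylation (0.169) and the citric acid cycle (0.348) and the genotype list for erythrocytes (0.318) were not called. Without array 3 of the sufficient group labelled Lrat-/-, the diet list for antigen presentation was not called (0.294).

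Leaving out 1 array gave 0 to 0 genes for diet, 7 to 27 for genotype, 7 to 32 for combined and 8 to 12 in any group, and 5 to 9, 10 to 16 and 15 to 19 lists for diet, genotype and combined. Without wild-type array 1 genotype called 27, and without wild-type array 3 it called 17 and combined 32. Without array 1 or array 2 of the deficient group combined called 7. Lrat then ranged from 1.42 to 1.64 for genotype, 1.29 to 1.41 for combined and -0.29 to -0.07 for diet.

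The replicate block called 10 genes for genotype, including all 8, and 20 for combined, including 14 of the 15. It changed the calls of Cdc14b (genotype, adjusted p = 0.0184) and Rerg (combined, 0.0588) and brought the circadian list of the combined comparison past the threshold (0.0378 against 0.0759). It changed no other call among the named genes and lists of the diet, genotype and combined comparisons. The lowest signals lie near the level of the background controls, whose median was 5.29 to 5.69, so a fall that ends there, as for Gdpd3 at 5.84, Elovl7 at 5.52 and Retnla at 5.42, has its size limited by the background.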

Other observations

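The comparison of all 6 arrays labelled Lrat-/- with wild type, the test for neighbouring genes, and the choice of the genes named here were made only after the results were seen.

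With both groups labelled Lrat-/- averaged, limma called 19 genes, 11 higher and 8 lower. With the replicate number as a block it called 32, 12 higher and 20 lower, with 17 of the 19 among them. Besides those called in the other comparisons, Pdpn, a surface glycoprotein of lymphatic and mesothelial cells, fell (log2 -0.59, adjusted p = 0.0400), as did the potassium channel Kcnj14 (-0.71, adjusted p = 0.0400). The phosphatase Cdc14b (0.98, adjusted p = 0.0400), the pseudouridine synthase Pus7 (0.45, adjusted p = 0.0493) and G730007D18Rik (0.65, adjusted p = 0.0322) rose. Leaving out 1 array gave 9 to 47 genes, with 47 without wild-type array 1, 45 without wild-type array 3, and 9 without array 1 or 2 of the deficient group or array 1 of the sufficient group labelled Lrat-/-.

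Single members of lists that did not pass as sets passed when adjusted over the list alone, which is not corrected across lists. None of those named next passed over all genes. In the genotype comparison the growth factor binding protein gene Igfbp5 fell (log2 -0.66, adjusted p = 0.00461) and the myelin gene Mal rose (0.59, adjusted p = 0.0397). In the combined comparison the interferon genes Mx2 (0.40, adjusted p = 0.0461) and Ifi204 (0.44, adjusted p = 0.0461) rose. Markers of atrium, adipocytes, nerve, B cells, T cells and neutrophils did not pass as lists in any of the 3 comparisons.

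Several genes that differ between arrays labelled Lrat-/- and wild type lie near one another. A candidate explanation is that the groups differ in chromosome segments from another strain. Of the 48 genes with an adjusted p under 0.1 in 6 arrays against 3 that have a place in the gene order, 10 had another within 20 places, against a median of 4 and a 95th percentile of 8 in 10000 random draws (one-sided permutation p = 0.0368). The pairs included Zfp52 and Zfp943, Chd6 and Pkig, and Plekha7 and Tmc7. The members of 3 of all 5 pairs changed in opposite directions. Related sequences such as the zinc finger genes, or shared control of neighbours, may also give such pairs, and the test does not separate these. The fixed list of 15 genes known to vary between strains did not pass in the genotype comparison (camera adjusted p = 0.539). Camera looks for a shift in 1 direction, so rises and falls within the list could cancel, and this result cannot decide the question.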
